A study of Mus musculus with 9 samples.

How the data were processed

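The tables used here are those of the series as deposited: gene counts, FPKM (fragments scaled by gene length and library total) and gene lengths for 9 libraries. Per the labels, total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. The authors made the count values from aligned reads, with TopHat2, HISAT2 and HTSeq named in the labels and GRCm39 as the genome; which aligner made the alignments used, the versions and the strandedness are not given in the sources used here. The authors scaled the FPKM values by gene length and library total before they were deposited, and recomputing them from the deposited counts, lengths and totals gave a largest relative difference of 1.6e-07. The length, position, strand and name columns, which hold other values, were taken as deposited and not changed. Coordinates are 1-based GRCm39 positions from the deposited table. FPKM served only for this check, and all tests used counts.

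Groups, replicate numbers and most alternative settings were fixed before the data were examined, as were the comparisons, the 42 gene lists, the ranking by which genes are named and the thresholds. The 8 added lists (cerebellum, hindbrain, cortex, striatum, hormones, olfactory bulb, Y-linked genes and their X homologues), the test against a fold of 1.5 and the fit on autosomes were chosen after the data were seen. A further 2 lists, for cerebellum with hindbrain and for striatum, were written after those patterns were known but before the values of their members were seen.

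Of 21899 genes measured, 3516 had no count in any library and 14837 passed filterByExpr and were tested. Counts were fitted with edgeR quasi-likelihood on all 9 libraries with a mean per group and TMM factors (0.982 to 1.03), and the 3 comparisons were contrasts of that fit. The common biological coefficient of variation was 4.15% (median over genes 5.3%), with 6 residual and 43.4 prior degrees of freedom, so the spread of a gene was drawn strongly toward the trend over genes. Without the filter the prior degrees of freedom were infinite, and no spread of single genes entered the p-values of that fit. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested within a comparison, and a gene changed when its edgeR adjusted p was under 0.05. The count adjusted over the list alone applies the same correction to the members of a list. CPM are counts scaled to the library total after TMM. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Named genes are Acod1, the 10 largest rises and falls among changed genes with a group mean of at least 1 CPM and no overlap between the groups (unnamed gene models were skipped, 1 fall at 1 day and 2 falls at 7 days against PBS), up to 4 members per list by p-value and up to 2 that changed against the direction of their list. Some genes that this rule names are not reported here.

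Lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 40 tested lists, and again with an estimated correlation and with fry. The added lists were adjusted among themselves. For LPS against PBS at 1 day, the calls that hold with an estimated correlation are cytokines, interferon-stimulated genes, TLR4 and NF-kB signalling, complement, antigen presentation, acute phase, reactive astrocytes, activated endothelium, glucocorticoid-responsive genes, PVT neurons, and hypothalamus and striatum. For LPS at 7 days against PBS they are interferon-stimulated genes, choroid plexus, GABAergic genes, hypothalamus and striatum, circadian clock, glucocorticoid-responsive genes and myelin. For 7 days against 1 day they are cytokines, interferon-stimulated genes, TLR4 and NF-kB signalling, complement, antigen presentation, acute phase, reactive astrocytes, circadian clock, glucocorticoid-responsive genes and myelin. Neutrophils (3 tested members) and lymphocytes (2) were too small for a set test.

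Genes without a count in a group are given as at least a fold, with 3 counts over the group as the floor. Genes with 1 to 3 counts in a group are given with a 95% counting interval of the ratio. Median, mean and set test of a list differed in sign only for lists without a call. At 1 day these were choroid plexus (0.00, -0.05, up), glycolysis and hypoxia (-0.04, 0.09, down) and heat shock (-0.08, 0.00, down). At 7 days against PBS they were general neuronal (-0.05, 0.01, down), sleep (0.02, -0.13, down), inflammasome (0.01, 0.01, down), complement (-0.02, 0.12, up), activated endothelium (0.00, 0.07, up) and hormones (-0.02, 0.19, up). At 7 days against 1 day they were glutamatergic (-0.12, 0.05, down), other thalamic nuclei (-0.27, 0.12, down), habenula (0.01, 0.06, down), hypothalamus and striatum (0.18, 0.12, down) and monocytes (-0.31, 0.06, down).

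The method was tested on simulated counts with 200 changed genes per comparison. At a log2 fold change of 0.5, 1 and 2 it recovered 76.9%, 86.6% and 100% in the first comparison, 74.6%, 95.5% and 100% in the second and 71.2%, 86.4% and 97% in the third, with 4.95%, 5.26% and 4% false calls. Of 5 shifted lists 5 were recovered, with 0 lists called without a shifted member. Simulated genes varied independently, so this does not show false list calls where the genes of a list move together. The 200 changed genes were also far fewer than the 5287 to 8399 called in the data.

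Replicate numbers do not pair samples: deviations from the group mean correlated at -0.023 to 0.027 over the 9 pairs with the same number and at -0.04 to 0.057 over the others. The first 2 principal components held 50.9% and 27.7% of the variance. Mitochondrial genes took 4.43% to 5.38% of counts. Alternatives were RLE, library size and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the 6 libraries of a comparison alone, a 2-fold limit, a block on the replicate number and leaving out each library in turn. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.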

Results

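Transcript levels were measured by RNA sequencing in tissue of the paraventricular thalamus (PVT), a midline thalamic nucleus that takes part in arousal, of wild-type mice. The mice had received lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, or phosphate-buffered saline (PBS) in the peritoneal cavity. The 9 libraries fell into 3 groups of 3: PBS at 1 day, LPS at 1 day and LPS at 7 days. PBS at 7 days was not analysed here, so day and treatment coincide wherever LPS at 7 days is set against PBS. Each library held 13211422 to 17210526 gene counts, and levels are given as CPM (counts scaled to library size, mean ± SD, n = 3 per group). Replicates lay close together: across genes, which are not independent replicates, Spearman's rho was 0.991 to 0.992 within groups and 0.981 to 0.986 between groups. Every pair within a group still differed by more than sampling noise (chi-square per degree of freedom 2.02 to 3.71). The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

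Y-linked and regional transcripts separate the groups beyond day and treatment. Y-linked genes together had 1, 0 and 0 counts in the 3 PBS libraries, where 0 counts allow up to 0.189 and 0.204 CPM, and 80.2 to 105 CPM in the 6 LPS libraries (these CPM use plain library totals). The labels used here give no sex. Transcripts typical of cerebellum and hindbrain were higher in all 3 LPS libraries at 7 days than in the 1 day libraries. An example was Gabra6, a GABA receptor subunit of cerebellar granule cells, which had 0.0861 ± 0.0435 CPM in PBS, 0.0203 ± 0.0351 CPM 1 day after LPS and 164 ± 3.82 CPM at 7 days. Intervals and floors cover counting error only.

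Acod1, the gene in the series title, encodes the mitochondrial enzyme that makes itaconate from cis-aconitate and lies on chromosome 14 (103284413 to 103294009, GRCm39). It was rare in every library, with 1, 0 and 1 counts in PBS, 8, 12 and 9 counts 1 day after LPS and 0, 3 and 0 counts at 7 days (0.0423 ± 0.0369, 0.637 ± 0.102 and 0.0617 ± 0.107 CPM). The level at 1 day was 15.2 times that in PBS (95% counting interval 3.83 to 131), and all 3 libraries lay above all 3 PBS libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow). The gene fell under the count minimum; without that filter its log2 fold change was 3.69 ± 0.99 (SE, edgeR quasi-likelihood adjusted p = 0.00087). That fit had infinite prior degrees of freedom, so this p-value and those without the filter for 7 days rest on the spread pooled over all genes and not on that of Acod1; DESeq2 gave an adjusted p of 0.00872. At 7 days the level was 0.0951 of its 1 day value (interval 0.0185 to 0.307, exact permutation p = 0.1, log2 fold change without the filter -3.23 ± 0.92, edgeR quasi-likelihood adjusted p = 0.00149, and -6.35 without LPS 7 day replicate 2). At 7 days the ratio to PBS was 1.44 (interval 0.165 to 17.3), and a difference was not detectable at this depth (exact permutation p = 1, log2 fold change 0.47 ± 1.48, edgeR quasi-likelihood adjusted p = 0.868). All 3 counts at 7 days came from replicate 2, and without that library the log2 fold change against PBS was -2.66. The 7 day group then holds no count, so neither this -2.66 nor the -6.35 against 1 day is a measured size.

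**Figure D1:**
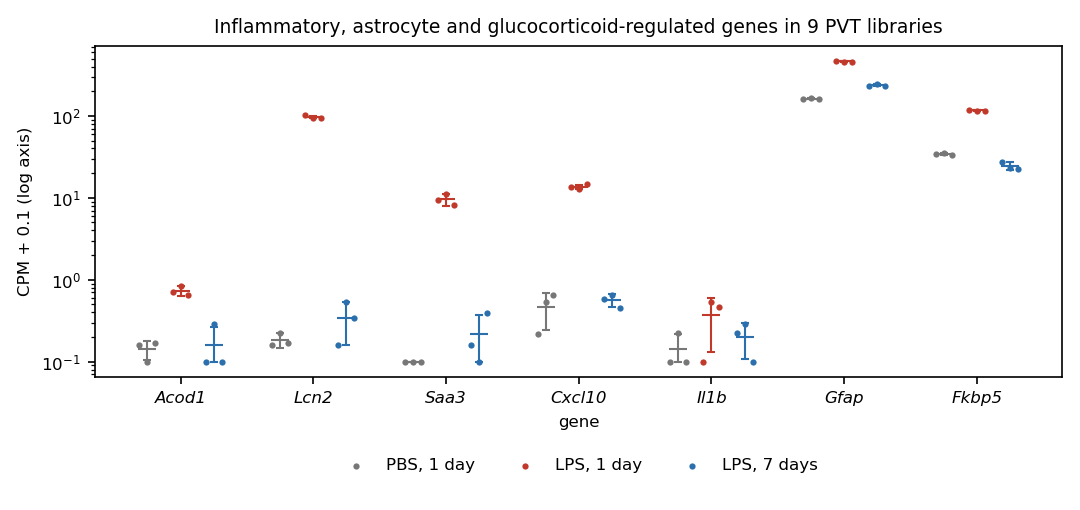
CPM plus 0.1 on a log axis for Acod1 and 6 other genes in the 9 libraries; points are libraries, dashes and bars the group mean ± SD (n = 3). Lcn2 had 0.0845 CPM in PBS, 97.2 CPM 1 day after LPS and 0.243 CPM at 7 days.

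The first comparison, LPS against PBS at 1 day, asks what differs in this tissue 24 hours after systemic LPS. Transcripts of other regions were abundant in PBS too. Lists of striatal and cortical genes, written after the data were seen, had mean log2 CPM of 7.15 to 7.17 and 6.44 to 6.53 there. Changes below thus cannot be assigned to the PVT alone. Innate immune transcripts rose together: Lcn2, which encodes a secreted protein that binds bacterial iron carriers, stood at 97.2 ± 3.37 CPM against 0.0845 ± 0.0367 CPM in PBS, and Serpina3n, a protease inhibitor of reactive astrocytes with close paralogs whose shared reads were not measured, at 431 ± 7.05 against 68.4 ± 5.1 CPM. Gfap, the intermediate filament of astrocytes, rose from 162 ± 2.41 to 462 ± 11 CPM, and Fkbp5, a co-chaperone induced by glucocorticoids, from 34.3 ± 1.29 to 116 ± 1.69 CPM. Transcripts of striatal neurons and immediate early genes fell, such as Adora2a, an adenosine receptor of striatal projection neurons, from 119 ± 3.5 to 55.4 ± 4.24 CPM, and Arc, a synaptic gene driven by activity, from 151 ± 2.45 to 65.2 ± 2.14 CPM. These 6 genes had edgeR quasi-likelihood adjusted p-values from 1.34e-42 to 5.33e-23. Of 14837 genes tested, 7289 (49.1%) changed by edgeR, 3699 up and 3590 down, and the split turned with library size scaling (3446 up, 3878 down) and upper-quartile scaling (3397 up, 3935 down). The median absolute log2 fold change was 0.36; 593 rose and 179 fell at least 2-fold. In 8082 genes (54.5%) the 3 libraries of each group did not overlap, where chance gives 10%. Among the 40 lists tested, 16 rose and 8 fell by camera. Counts adjusted over the list alone are given where they differ from those over all genes tested.

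Immune lists rose 1 day after LPS. All 9 tested members of the acute phase list rose (median log2 fold change 2.65, unchanged with Saa3 at its bound, camera adjusted p = 1.75e-08). Saa3, which encodes a serum amyloid, had no count in PBS and 9.49 ± 1.56 CPM after LPS, at least 150-fold higher against a floor of 3 counts over the group, and Cp, the copper carrier ceruloplasmin, had a log2 fold change of 1.60 ± 0.08. Of 31 interferon-stimulated genes 30 rose and 1 did not pass (median 1.98, camera adjusted p = 2.23e-17), among them Irgm1 and Oasl2, antimicrobial proteins induced by interferon, at 2.55 ± 0.10 and 2.29 ± 0.10. Of 9 tested cytokines and chemokines 7 rose, 1 fell and 1 did not pass (median 2.62, camera adjusted p = 0.00142). Cxcl10, which attracts T cells, stood at 13.6 ± 0.838 against 0.369 ± 0.223 CPM, whereas Il18 fell by 0.65 ± 0.11. Classical cytokines were near the floor and not tested. Over the groups, in the order PBS, LPS at 1 day and LPS at 7 days, Il1b had 2, 13 and 5 counts, Tnf 0, 8 and 3, and Il6 2, 8 and 3. These 3 genes were chosen after their values were seen. The complement and coagulation list (14 of 18 up, 4 not passed, median 1.08, camera adjusted p = 1.54e-07) included C1qb, a subunit of the first complement component, at 1.19 ± 0.08 and Serping1, its inhibitor, at 2.08 ± 0.13. For antigen presentation 15 of 18 members rose (16 adjusted over the list alone), 1 fell and 2 did not pass (median 0.98, camera adjusted p = 1.17e-06), including Tap1, a peptide transporter, at 2.43 ± 0.13. In the TLR4 and NF-kB list 15 of 25 rose and 10 did not pass (median 0.41, camera adjusted p = 2.07e-06), with the LPS co-receptor Cd14 at 1.93 ± 0.18. The inflammasome and pyroptosis list had 6 of 11 up, 1 down and 4 not passed (median 0.92, camera adjusted p = 0.0307). For this list the camera adjusted p was 0.0879 with an estimated correlation and 0.0579 without PBS replicate 3. Nek7, a kinase of the NLRP3 inflammasome, was at 0.92 ± 0.07. All of these groups were compared between libraries that also differ in Y-linked transcripts.

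Lists of glial and vascular genes changed as well. Some share members with the immune lists, such as Lcn2, Cp and Cxcl10 for reactive astrocytes and Lrg1 and Csf3 for activated endothelium. They are thus not independent of the immune lists, and whole tissue does not show which cells changed. Of 33 tested reactive astrocyte genes 26 rose (27 adjusted over the list alone), 1 fell and 6 did not pass (median 1.72, camera adjusted p = 1.84e-12), including Gfap at 1.51 ± 0.04. Genes of activated microglia and macrophages rose in 14 of 23 cases, fell in 1 and did not pass in 8 (median 0.59, camera adjusted p = 0.000174, and camera adjusted p = 0.0646 with an estimated correlation). Msr1, a scavenger receptor, had 4.99 ± 0.409 against 0.192 ± 0.174 CPM. Homeostatic microglial genes split, with 3 up, 7 down (8 adjusted over the list alone) and 6 not passed of 16 (median -0.18, camera adjusted p = 0.155). The purinergic receptor P2ry12 fell by 1.03 ± 0.08 and the phagocytic receptor Mertk rose by 0.44 ± 0.07. Activated endothelium had 11 of 16 up and 5 not passed (median 0.98, camera adjusted p = 3.22e-05). The leukocyte adhesion molecule Icam1 was at 2.40 ± 0.17 and Lrg1 at 3.29 ± 0.23. Fibroblasts and meninges had 7 of 12 up, 1 down and 4 not passed (median 0.44, camera adjusted p = 0.0221, and camera adjusted p = 0.0746 with an estimated correlation), such as the collagen gene Col1a2 at 0.81 ± 0.10. Among 5 tested monocyte genes 3 rose (4 adjusted over the list alone) and 2 did not pass (median 0.65, camera adjusted p = 0.0103, and camera adjusted p = 0.068 with an estimated correlation), with lysozyme, Lyz2, at 1.13 ± 0.23. Oligodendrocyte genes fell: 13 of 18 myelin genes fell, 3 rose and 2 did not pass (median -0.35, camera adjusted p = 0.000718, and camera adjusted p = 0.0579 with an estimated correlation). The gap junction gene Gjb1 was at -1.06 ± 0.10 and, against the list, Mobp at 0.33 ± 0.03. Of 15 genes of oligodendrocyte precursors and newly formed oligodendrocytes 9 fell, 4 rose and 2 did not pass (median -0.32, camera adjusted p = 0.0402, and camera adjusted p = 0.0936 with an estimated correlation and 0.0525 without LPS 7 day replicate 3). The transcription factor Olig1 was at -0.66 ± 0.04. The Y-linked difference holds here too.

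All 19 glucocorticoid-responsive genes tested rose 1 day after LPS (median 0.87, camera adjusted p = 1.84e-12), for example the cell cycle inhibitor Cdkn1a at 2.23 ± 0.07 and the lipid droplet gene Plin4 at 2.74 ± 0.11. Immediate early genes fell in 19 of 22 cases, rose in 2 and did not pass in 1 (median -0.67, camera adjusted p = 4.24e-08, and camera adjusted p = 0.0646 with an estimated correlation). Egr1 and Fos, transcription factors induced by activity, were at -1.17 ± 0.05 and -1.16 ± 0.07, while Per1, also a clock gene and a glucocorticoid target, rose by 0.62 ± 0.04. Neuronal and regional lists mostly fell. The PVT neuron list fell in 13 of 23 members, rose in 1 and did not pass in 9 (median -0.40, camera adjusted p = 0.000791), including the dopamine receptor Drd2 at -1.03 ± 0.06, which striatal neurons also express, and the calcium buffer Calb2 at -0.40 ± 0.05. The hypothalamus and striatum list fell in 16 of 18 members with 2 not passed (median -0.74, camera adjusted p = 4.35e-07), with Adora2a and the G protein regulator Rgs9 at -1.10 ± 0.05 and -0.76 ± 0.05. Other thalamic nuclei (14 of 21 down, 3 up, 4 not passed, median -0.28, camera adjusted p = 0.0051, and camera adjusted p = 0.0662 with an estimated correlation) included the sodium channel subunit Scn4b at -0.56 ± 0.04. The habenula list (8 of 16 down, 8 not passed, median -0.27, camera adjusted p = 0.0247, and camera adjusted p = 0.0746 with an estimated correlation) included Nwd2 at -0.69 ± 0.07. GABAergic genes fell in 13 of 21 cases (14 adjusted over the list alone), rose in 3 and did not pass in 5 (median -0.18, camera adjusted p = 0.0294, and camera adjusted p = 0.0758 with an estimated correlation). The vesicular transporter Slc32a1 was at -0.46 ± 0.05. The hippocampus and dentate gyrus list rose in 7 of 14 members, fell in 1 and did not pass in 6 (median 0.23, camera adjusted p = 0.0458). For this list the camera adjusted p was 0.33 with an estimated correlation, 0.0936 without PBS replicate 3 and 0.133 without LPS 1 day replicate 2. The transcription factor Neurod2 was at 0.75 ± 0.07. Beside these regional shifts, 13 of 15 members of a striatum list written after the data were seen fell and 2 did not pass (median -0.72, camera adjusted p = 6.15e-09), and the same libraries differ in Y-linked transcripts.

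Lists tied to the series title gave no camera call 1 day after LPS. The itaconate, TCA cycle and related enzymes list had 2 up, 8 down and 17 not passed of 27 (0 up and 7 down adjusted over the list alone, median -0.06, camera adjusted p = 0.263). The mitochondrial citrate carrier Slc25a1 was at -0.53 ± 0.07 and Ogdh, a TCA cycle subunit, at -0.31 ± 0.04. Of 26 NRF2 targets and oxidative stress genes 11 rose, 3 fell and 12 did not pass (median 0.10, camera adjusted p = 0.0799, but camera adjusted p = 0.0413 without LPS 1 day replicate 1), among them the cystine transporter Slc7a11 at 0.50 ± 0.07. Oxidative phosphorylation had 1 up, 7 down (6 adjusted over the list alone) and 21 not passed of 29 (median -0.06, camera adjusted p = 0.195). Sleep, prostaglandin and adenosine genes had 9 up, 3 down and 12 not passed of 24 (median 0.06, camera adjusted p = 0.184). Ptgds, a prostaglandin D synthase, rose by 0.78 ± 0.04 and the interleukin-1 receptor Il1r1 by 1.54 ± 0.13. No camera call was made either for homeostatic astrocytes (9 up, 6 down, 3 not passed, median 0.07, camera adjusted p = 0.23), endothelium and blood-brain barrier (8 up, 8 down, 4 not passed, 0.03, 0.849), pericytes and vascular smooth muscle (4 up, 2 down, 7 not passed, -0.05, 0.997) or choroid plexus and ependyma (2 up, 1 of them adjusted over the list alone, 3 down, 11 not passed, 0.00, 0.997). General neuronal genes (3 up, 4 adjusted over the list alone, 9 down, 6 not passed, median -0.11, camera adjusted p = 0.144) and the glutamatergic synapse (8 up, 13 down, 3 not passed, -0.19, 0.135) likewise gave none.

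By the fixed ranking, the largest rises at 1 day after LPS, apart from Lcn2 and Saa3, were Y-linked Ddx3y (Y chromosome, 1260771 to 1286629, at least 449-fold), Eif2s3y (at least 344-fold), Uty (at least 171-fold) and Kdm5d (1050 times, 95% counting interval 188 to 41400), then Vmn2r84 (at least 18.1-fold), Hao1 (136 times, 24 to 5410), the bile acid family transporter Slc10a6 (115 times, 31.6 to 959) and Crtam (106 times, 28.8 to 877). Among the largest falls were the pituitary hormone gene Prl, from 4.59 ± 0.084 to 0.718 ± 0.187 CPM, Gkn3, from 2.32 ± 0.499 to 0.301 ± 0.22 CPM, and Ankk1, the neighbour of Drd2, from 4.17 ± 0.731 to 0.789 ± 0.237 CPM (edgeR quasi-likelihood adjusted p = 1e-12, 1.5e-07 and 1.03e-09). Prl may come from tissue outside the PVT, which was not tested. A test against a fold of 1.5, chosen after the data were seen, called 647 genes.

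The second comparison, LPS at 7 days against PBS at 1 day, asks what differs from PBS a week after LPS. Day, Y-linked level and cerebellar and hindbrain transcripts differ too, so a difference need not be a lasting effect of LPS. Lcn2 and Cxcl10, named for their change at 1 day, had 0.243 ± 0.185 and 0.467 ± 0.102 CPM against 0.0845 ± 0.0367 and 0.369 ± 0.223 CPM in PBS. Gfap was above PBS (238 ± 6.83 against 162 ± 2.41 CPM, log2 fold change 0.55 ± 0.04, edgeR quasi-likelihood adjusted p = 4.06e-17), and the major myelin gene Mbp was at 5170 ± 363 against 3670 ± 203 CPM (0.50 ± 0.04). Whether tissue of other regions brought the higher Gfap and Mbp was not tested. Transcripts of striatal projection neurons fell, with Adora2a at 51.8 ± 1.02 and the phosphatase regulator Ppp1r1b at 120 ± 3.27 CPM against 119 ± 3.5 and 304 ± 9.9 CPM in PBS. Y-linked, cerebellar and hindbrain transcripts were among the largest rises, with Ddx3y at least 508-fold higher and Cbln3 going from 0.483 ± 0.081 to 315 ± 2.75 CPM. Changed genes numbered 5287 of 14837 (35.6%), 2489 up and 2798 down by edgeR, with a median absolute log2 fold change of 0.34; scaling by library size alone gave 3183 up and 2326 down. At least 2-fold, 361 rose and 180 fell, and in 6563 genes (44.2%, where chance gives 10%) the libraries of the groups did not overlap. Of 40 lists, 5 rose and 11 fell by camera.

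Cerebellar and hindbrain genes were higher at 7 days than in PBS. All 20 members of a cerebellum list and all 12 tested members of a hindbrain list, both written after the pattern was seen, rose against PBS (median log2 fold changes 3.82 and 7.45, the latter 4.71 with 9 genes at their bound, camera adjusted p = 1.15e-24 and 1.89e-14). Gabra6 (chromosome 11, 42197264 to 42211899) and Fat2, a cadherin of granule cell axons, had log2 fold changes of 10.80 ± 0.15 and 10.39 ± 0.14, and Tlx3, a hindbrain and spinal cord transcription factor, was at least 73.3-fold higher. Within the fixed lists the members that rose against their list's direction included genes of the cerebellum: Cbln1 and Zic1 among other thalamic nuclei at 2.35 ± 0.05 and 1.35 ± 0.04, Pvalb among GABAergic genes at 2.16 ± 0.06, Grm4 in the glutamatergic list at 1.51 ± 0.05 and Calb1 among PVT neurons at 0.71 ± 0.04. Neuronal lists with a camera call fell. Other thalamic nuclei had 16 down, 4 up and 1 not passed of 21 (median -0.46, camera adjusted p = 0.00248, and camera adjusted p = 0.0774 with an estimated correlation). Scn4b was at -1.23 ± 0.04. PVT neuron genes had 12 down (13 adjusted over the list alone), 3 up and 8 not passed of 23 (median -0.39, camera adjusted p = 0.0219, and camera adjusted p = 0.0961 with an estimated correlation). Drd2 was at -1.08 ± 0.06. Hypothalamus and striatum genes had 10 down, 1 up (2 adjusted over the list alone) and 7 not passed of 18 (median -0.56, camera adjusted p = 6.64e-05), and GABAergic genes 14 down, 2 up and 5 not passed of 21 (median -0.30, camera adjusted p = 0.00046). The peptide gene Sst was at -0.68 ± 0.05. The habenula list had 8 down, 2 up (3 adjusted over the list alone) and 6 not passed of 16 (median -0.36, camera adjusted p = 0.0219, and camera adjusted p = 0.0993 with an estimated correlation). The peptide gene Tac1 was at -0.73 ± 0.08. The glutamatergic synapse had 16 down (17 adjusted over the list alone), 4 up and 4 not passed of 24 (median -0.22, camera adjusted p = 0.0104, and camera adjusted p = 0.442 with an estimated correlation). The kinase gene Camk2a was at -0.66 ± 0.03. On the striatum list written afterwards all 15 members fell (median -1.16, camera adjusted p = 1.89e-17), and on the cortex list 11 of 15 fell and 4 did not pass (median -0.41, camera adjusted p = 4.98e-06).

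**Figure D2:**
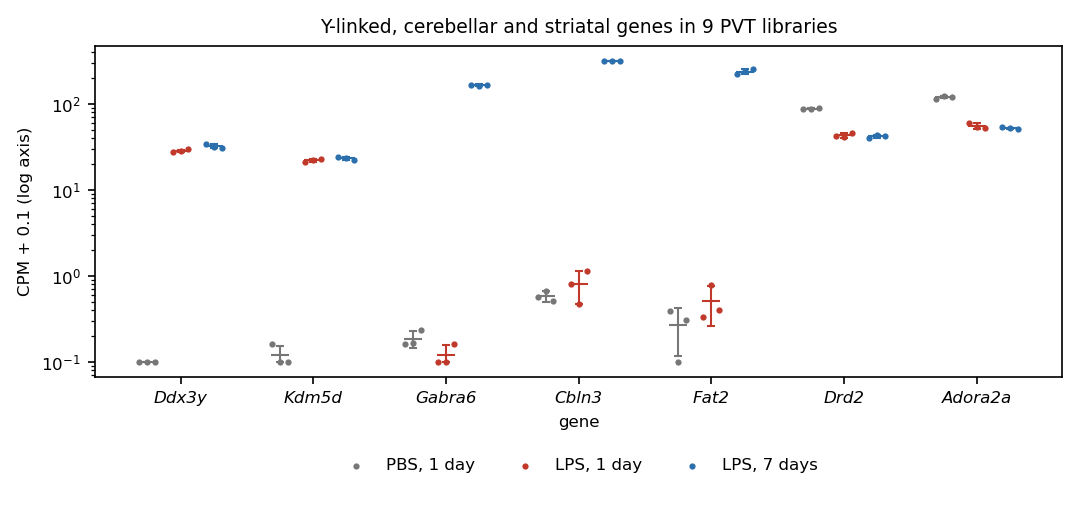
CPM plus 0.1 on a log axis for Y-linked (Ddx3y, Kdm5d), cerebellar (Gabra6, Cbln3, Fat2) and striatal genes (Drd2, Adora2a) in the 9 libraries; points are libraries, dashes and bars the group mean ± SD (n = 3). Cbln3 had 0.483 CPM in PBS, 0.701 CPM 1 day after LPS and 315 CPM at 7 days, and Adora2a had 119, 55.4 and 51.8 CPM.

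Immune lists at 7 days held a single camera call, the interferon-stimulated genes, which fell below PBS in 14 of 31 members, rose in 1 and did not pass in 16 (median -0.40, camera adjusted p = 0.000445). Ifit1 and Irf7, antiviral genes, were at -1.53 ± 0.20 and -1.27 ± 0.20. No call was made for cytokines and chemokines (0 up, 1 down, 8 not passed, median -0.19, camera adjusted p = 0.733), TLR4 and NF-kB signalling (4 up, 3 down, 18 not passed, 0.07, 0.424), inflammasome and pyroptosis (0 up, 1 down, 10 not passed, 0.01, 0.962), complement and coagulation (4 up, 2 down, 12 not passed, -0.02, 0.616), antigen presentation (6 up, 2 down, 10 not passed, 0.01, 0.469) or acute phase proteins (2 up, 1 down, 6 not passed, 0.08, 0.683). Activated microglia and macrophages (3 up, 2 down, 18 not passed, median 0.03, camera adjusted p = 0.553) and homeostatic microglia (3 down, 13 not passed, -0.13, 0.147) gave none either, although Spp1, osteopontin, rose by 1.94 ± 0.12. Reactive astrocytes had 8 up, 2 down and 23 not passed (median 0.17, camera adjusted p = 0.0734, but camera adjusted p = 0.0436 without PBS replicate 2). The filament gene Vim was at 0.87 ± 0.07. Homeostatic astrocyte genes rose in 10 of 18 cases (11 adjusted over the list alone), fell in 3 and did not pass in 5 (median 0.22, camera adjusted p = 0.00328, and camera adjusted p = 0.0575 with an estimated correlation), among them the water channel Aqp4 at 0.70 ± 0.04. Myelin genes rose in 13 of 18 cases (14 adjusted over the list alone) with 5 not passed (median 0.29, camera adjusted p = 4.48e-05), Mobp by 0.58 ± 0.03. Pericytes and vascular smooth muscle had 7 of 13 up and 6 not passed (median 0.17, camera adjusted p = 0.00571, and camera adjusted p = 0.128 with an estimated correlation). Rgs5 was at 0.82 ± 0.05. Choroid plexus and ependyma fell in 12 of 16 members with 4 not passed (median -0.49, camera adjusted p = 8.23e-05), including Kl at -1.29 ± 0.08. Glucocorticoid-responsive genes fell below PBS in 14 of 19 cases with 5 not passed (median -0.45, camera adjusted p = 5.69e-07), Sgk1, a kinase gene on chromosome 10 (21758083 to 21875802), by 1.31 ± 0.04. Immediate early genes fell in 16 of 22 cases (17 adjusted over the list alone) with 6 not passed (median -0.39, camera adjusted p = 2.88e-07, and camera adjusted p = 0.0961 with an estimated correlation), Egr1 by 0.73 ± 0.05. The glial, vascular and endocrine groups here moved together with the cerebellar and the Y-linked transcripts.

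Mitochondrial lists rose slightly at 7 days. The itaconate, TCA cycle and related enzymes list had 14 up (15 adjusted over the list alone), 2 down and 11 not passed of 27 (median 0.12, camera adjusted p = 0.0267). For this list the camera adjusted p was 0.47 with an estimated correlation, 0.0907 without PBS replicate 1 and 0.06 without LPS 7 day replicate 1. The succinate-CoA ligase gene Suclg1 was at 0.23 ± 0.06 and, against the list, the malate dehydrogenase gene Mdh2 at -0.30 ± 0.04. Oxidative phosphorylation had 13 of 29 up (14 adjusted over the list alone) and 16 not passed (median 0.15, camera adjusted p = 0.00259, and camera adjusted p = 0.321 with an estimated correlation). Ndufa4 was at 0.31 ± 0.05. NRF2 targets and oxidative stress (5 up, 4 adjusted over the list alone, 1 down, 20 not passed, median 0.02, camera adjusted p = 0.469) and sleep, prostaglandin and adenosine signalling (3 up, 5 down, 16 not passed, 0.02, 0.616) gave no call; in the latter the histamine receptor Hrh3 fell by 0.85 ± 0.06. Nor was there one for endothelium and blood-brain barrier (6 up, 2 down, 12 not passed, median 0.12, camera adjusted p = 0.0734, but camera adjusted p = 0.0495 without LPS 7 day replicate 1), activated endothelium (3 up, 13 not passed, 0.00, 0.469), fibroblasts and meninges (4 up, 5 adjusted over the list alone, 1 down, 2 adjusted over the list alone, 7 not passed, 0.32, 0.149), monocytes (3 up, 1 down, 1 not passed, 0.16, 0.261) or oligodendrocyte precursors and newly formed oligodendrocytes (5 up, 4 down, 6 not passed, 0.09, 0.553). General neuronal genes (7 up, 8 down, 3 not passed, median -0.05, camera adjusted p = 0.779) and hippocampus and dentate gyrus (4 up, 4 down, 6 not passed, 0.02, 0.954) completed the lists without a call. The largest falls by the fixed ranking included Prss56, from 2.29 ± 0.378 to 0.122 ± 0.0624 CPM, Pnpla1, from 6.11 ± 0.695 to 1.2 ± 0.436 CPM, and Cdhr1, a cadherin of olfactory bulb neurons, from 34.7 ± 1.08 to 8.32 ± 1.4 CPM (edgeR quasi-likelihood adjusted p = 5.12e-10, 9.79e-12 and 4.1e-23). With no PBS group at 7 days, differences of day, treatment, tissue makeup and Y-linked level coincide in this comparison.

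The third comparison, LPS at 7 days against LPS at 1 day, tests the change over the week directly, since PBS cancels, and both groups carry Y-linked transcripts (Ddx3y at 28.3 ± 0.899 and 32.1 ± 1.91 CPM). Inflammatory transcripts fell: Lcn2 from 97.2 ± 3.37 to 0.243 ± 0.185 CPM, Serpina3n from 431 ± 7.05 to 75.5 ± 3.31 CPM and Cxcl10 from 13.6 ± 0.838 to 0.467 ± 0.102 CPM (edgeR quasi-likelihood adjusted p = 4.78e-43, 1.57e-42 and 2.48e-23). Glucocorticoid-responsive genes fell with them, Fkbp5 from 116 ± 1.69 to 24.2 ± 2.77 CPM and Sgk1 from 243 ± 3.62 to 67.6 ± 1.29 CPM. Myelin genes rose, such as Ugt8a, which makes myelin galactolipids, from 41.7 ± 1.12 to 106 ± 5.17 CPM, and the immediate early gene Arc rose from 65.2 ± 2.14 to 115 ± 1.61 CPM. Changed genes numbered 8399 of 14837 (56.6%), 4076 up and 4323 down by edgeR, and the split turned with library size scaling (4867 up, 3680 down) and upper-quartile scaling (4396 up, 4046 down). The median absolute log2 fold change was 0.41; 470 rose and 669 fell at least 2-fold. In 8994 genes (60.6%, where chance gives 10%) the libraries of the groups did not overlap. Of 40 lists, 6 rose and 13 fell by camera.

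Immune lists with a camera call fell between 1 and 7 days. All 31 interferon-stimulated genes fell (median -2.60, camera adjusted p = 2.27e-16), Oasl2 by 2.93 ± 0.10 and Irgm1 by 2.67 ± 0.10, as did all 9 tested acute phase genes (median -2.51, camera adjusted p = 8.93e-07), Lcn2 at -8.60 ± 0.15 and Saa3 at -6.20 ± 0.37. Of 9 cytokines and chemokines 8 fell (9 adjusted over the list alone) and 1 did not pass (median -3.92, camera adjusted p = 0.000898), Cxcl10 by 4.84 ± 0.24. Complement and coagulation had 16 of 18 down (17 adjusted over the list alone) and 2 not passed (median -1.07, camera adjusted p = 2.42e-06). C1qb was at -1.27 ± 0.08. Antigen presentation had 13 down, 1 up and 4 not passed of 18 (median -0.82, camera adjusted p = 0.000562). Tap1 was at -2.76 ± 0.13, and TLR4 and NF-kB signalling 14 down, 1 up and 10 not passed of 25 (median -0.38, camera adjusted p = 0.0024). Cd14 was at -2.02 ± 0.18 and, going up, the inhibitor gene Nfkbie at 0.99 ± 0.19. Inflammasome and pyroptosis had 5 down and 6 not passed of 11 (median -0.58, camera adjusted p = 0.0296, and camera adjusted p = 0.115 with an estimated correlation). Reactive astrocyte genes fell in 26 of 33 cases, rose in 2 (4 adjusted over the list alone) and did not pass in 5 (median -1.69, camera adjusted p = 5.02e-07), Gfap by 0.96 ± 0.04, while Vim rose by 0.43 ± 0.07. Activated microglia and macrophages had 12 down, 2 up and 9 not passed of 23 (median -0.54, camera adjusted p = 0.0159, and camera adjusted p = 0.234 with an estimated correlation). Msr1 was at -5.82 ± 0.47. Activated endothelium had 10 down, 1 up and 5 not passed of 16 (median -0.86, camera adjusted p = 0.00499, and camera adjusted p = 0.0524 with an estimated correlation). Icam1 was at -2.14 ± 0.16. All 19 glucocorticoid-responsive genes fell (median -1.36, camera adjusted p = 2.68e-13), Cdkn1a by 2.95 ± 0.08.

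**Figure D3:**
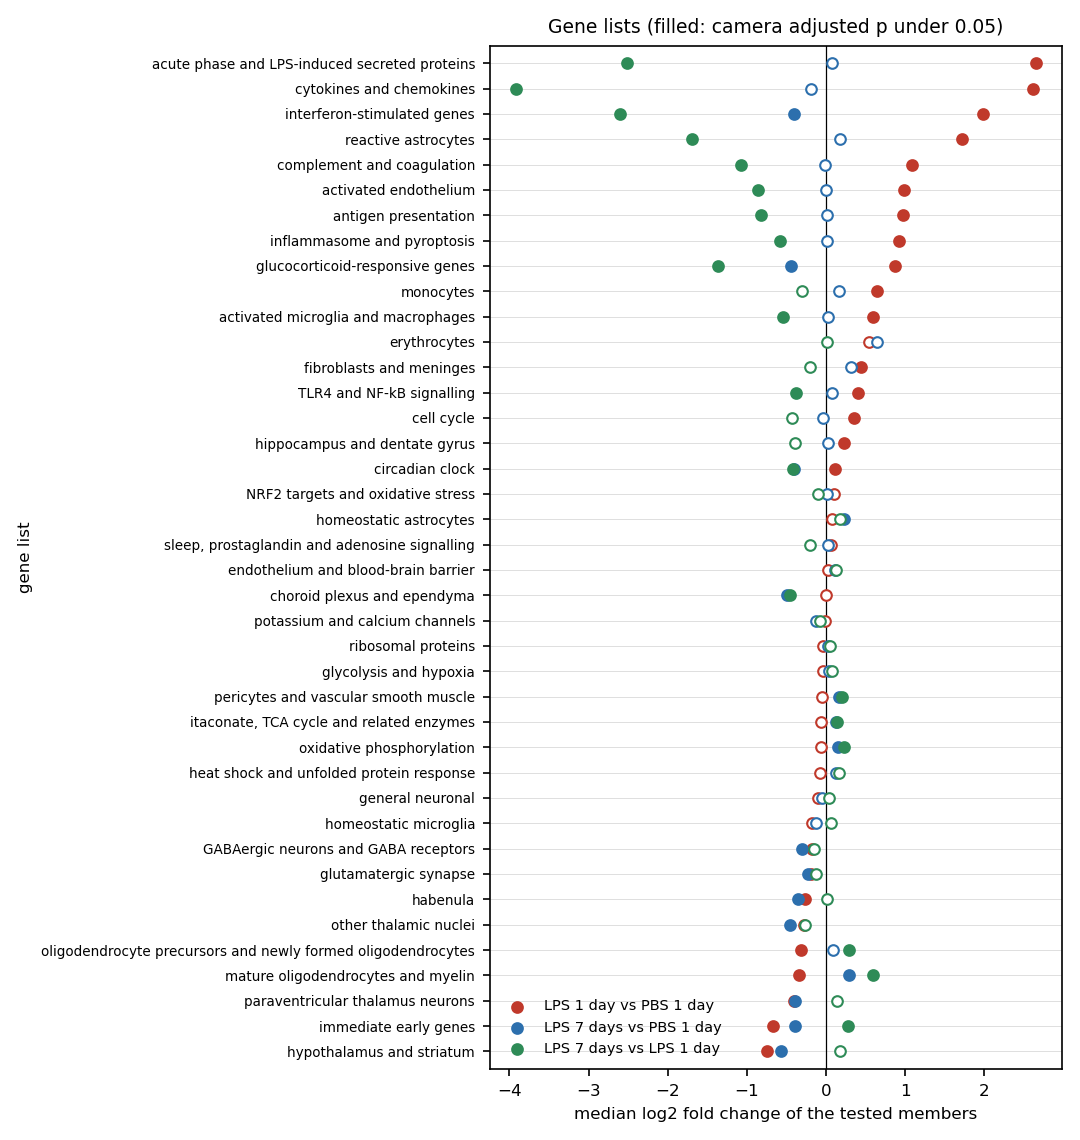
Median log2 fold change of the tested members of 40 gene lists fixed before the data were examined, in the 3 comparisons (colours); filled circles are lists with a camera adjusted p under 0.05. The cytokine list sits at 2.62 for LPS at 1 day against PBS and at -3.92 for 7 days against 1 day, and the myelin list at -0.35 and 0.60.

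Oligodendrocyte, mitochondrial and activity-driven genes rose over the week. Myelin genes rose in 16 of 18 cases and fell in 2 (median 0.60, camera adjusted p = 9.75e-07), Gjb1 by 1.59 ± 0.09 and Ugt8a by 1.35 ± 0.06. Oligodendrocyte precursors and newly formed oligodendrocytes had 9 up (10 adjusted over the list alone), 3 down and 3 not passed of 15 (median 0.29, camera adjusted p = 0.0296, and camera adjusted p = 0.115 with an estimated correlation). Olig1 was at 0.80 ± 0.04. Immediate early genes rose in 12 of 22 cases, fell in 3 (4 adjusted over the list alone) and did not pass in 7 (median 0.27, camera adjusted p = 0.0179, and camera adjusted p = 0.383 with an estimated correlation), Fos by 1.04 ± 0.07, while Per1 fell by 1.29 ± 0.04. Oxidative phosphorylation had 20 of 29 up and 9 not passed (median 0.22, camera adjusted p = 0.000764, and camera adjusted p = 0.252 with an estimated correlation). Cyc1, cytochrome c1, was at 0.57 ± 0.06. The itaconate, TCA cycle and related enzymes list had 17 up, 3 down and 7 not passed of 27 (median 0.14, camera adjusted p = 0.0133, and camera adjusted p = 0.383 with an estimated correlation). Slc25a1 was at 0.60 ± 0.07. The list of pericytes and vascular smooth muscle had 7 up, 2 down and 4 not passed of 13 (median 0.21, camera adjusted p = 0.0382). For this list the camera adjusted p was 0.249 with an estimated correlation and 0.0694 without LPS 1 day replicate 2. Rgs5 was at 0.87 ± 0.05. Choroid plexus and ependyma had 10 down, 1 up and 5 not passed of 16 (median -0.45, camera adjusted p = 0.0133, and camera adjusted p = 0.115 with an estimated correlation). Kl was at -1.46 ± 0.08. Beside these shifts, all 20 cerebellum and all 12 tested hindbrain members rose (medians 3.68 and 5.24, the latter 4.39 with 4 genes at their bound, camera adjusted p = 1.47e-17 and 4.11e-09), and striatum and cortex genes fell in 11 and 12 of 15 cases with 4 and 3 not passed (medians -0.37 and -0.43, camera adjusted p = 8.57e-06 and 5.75e-06).

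Lists with no camera call over the week included sleep, prostaglandin and adenosine signalling (3 up, 10 down, 11 not passed of 24, median -0.20, camera adjusted p = 0.0994), in which Nt5e, which makes extracellular adenosine, and the cyclooxygenase Ptgs2 fell by 1.87 ± 0.11 and 1.49 ± 0.13. PVT neurons (5 up, 6 down, 12 not passed of 23, median 0.14, camera adjusted p = 0.525) included Calb2 at 1.12 ± 0.05, and other thalamic nuclei (5 up, 11 down, 5 not passed of 21, -0.27, 0.394) included Cbln1 at 2.73 ± 0.05. No call was made for homeostatic microglia (6 up, 3 down, 7 not passed, median 0.07, camera adjusted p = 0.571), homeostatic astrocytes (10 up, 8 down, 0.18, 0.275), endothelium and blood-brain barrier (10 up, 7 down, 3 not passed, 0.13, 0.506), fibroblasts and meninges (1 up, 6 down, 5 not passed, -0.20, 0.3), monocytes (2 up, 3 down, -0.31, 0.494) or NRF2 targets and oxidative stress (6 up, 8 down, 12 not passed, -0.10, 0.511). General neuronal (9 up, 7 down, 2 not passed, median 0.04, camera adjusted p = 0.506), glutamatergic (9 up, 12 down, 3 not passed, -0.12, 0.506), GABAergic (7 up, 14 down, -0.15, 0.21), habenula (3 up, 3 down, 10 not passed, 0.01, 0.907), hippocampus and dentate gyrus (2 up, 7 down, 5 not passed, -0.39, 0.0917) and hypothalamus and striatum genes (7 up, 8 adjusted over the list alone, 6 down, 5 not passed, 0.18, 0.862) gave none either. By the fixed ranking the largest rises included Gabra6 (7450 times, 95% counting interval 1340 to 294000), Cnpy1, Fat2, Cbln3, Hoxa5 (at least 30.3-fold), Hoxc4 (at least 26.4-fold), Hoxa4 (at least 15.3-fold), Slc6a5 and Tlx3 (105 times, 28.8 to 875). The largest falls, after Lcn2, were Tigit (at least 18.5-fold lower), Ifi209 (197 times lower, 34.9 to 7820), Snorc (at least 17.4-fold lower), Itih4 (164 times lower, 29 to 6530), Hao1 (141 times lower, 24.9 to 5630), Csf3 (127 times lower, 22.4 to 5070), Saa3, Cyp3a57 (82.6 times lower, 14.4 to 3310) and Msr1. Any fall or rise in this comparison is measured between libraries that also differ in cerebellar transcripts.

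Most genes that had changed at least 2-fold at 1 day changed back by 7 days. Of the 593 genes that had risen at least 2-fold at 1 day, 489 (82.5%) fell between 1 and 7 days by edgeR, 110 (18.5%) were still above PBS and 43 were below it. The median share of the log2 fold change left at 7 days was 9.61% (share 0.096, SD 0.014 over the 3 libraries). Of the 179 that had fallen, 109 (60.9%) rose back, 65 (36.3%) were still below PBS and 11 were above it, and the median share left was 30.5% (share 0.305, SD 0.018). With no limit on the fold, 2721 of 3699 rises and 2276 of 3590 falls were called back and the share left of falls was 0.176, and the falls still present include the striatal genes Adora2a and Drd2. Both LPS comparisons use the same 3 PBS libraries. They shared 783 rising and 1118 falling genes, where independent lists would share 620.5 and 677. In 20 simulations of unchanged groups against shared controls the overlaps were 0 and 0. With no gene changed, overlaps near 0 are set in advance, so they do not measure what shared controls add. A further 606 rose at 1 day and fell at 7 days and 520 did the reverse (independent lists 697.6 and 602.2). Across genes the log2 fold changes correlated at 0.326 (0.5 in the simulations) with a covariance of 0.121 (simulated 0.0116). Part of the excess may come from the shared controls, because 3 controls cannot be split with at least 2 in each part. Both LPS groups also differ from PBS in Y-linked and striatal transcripts.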

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

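Tests on sex, on the first regional lists and with the filter on 1 day libraries were chosen after the results were seen, whereas those on the second regional lists and the splits of the libraries were written before their values were seen. The differences of LPS at 1 and at 7 days from the same PBS libraries were unlike for 24 lists by camera with a preset correlation and for 8399 genes by edgeR. For each list the difference was tested by camera on 7 days against 1 day, where PBS cancels. Of the 8399 genes, 1126 had changed against PBS in opposite directions at the 2 times. These were 606 that rose at 1 day and fell at 7 days and 520 the reverse, where independent lists would give 697.6 and 602.2.

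Lower at 7 days than at 1 day were the medians of cytokines and chemokines (-3.92), interferon-stimulated genes (-2.60), acute phase proteins (-2.51), reactive astrocytes (-1.69), glucocorticoid-responsive genes (-1.36), complement and coagulation (-1.07), activated endothelium (-0.86), antigen presentation (-0.82), inflammasome and pyroptosis (-0.58), activated microglia and macrophages (-0.54), choroid plexus and ependyma (-0.45), cortex (-0.43), circadian clock (-0.41), TLR4 and NF-kB signalling (-0.38) and striatum (-0.37). Higher were hindbrain (5.24), cerebellum (3.68), myelin (0.60), hypothalamic and pituitary hormones (0.60), oligodendrocyte precursors and newly formed oligodendrocytes (0.29), immediate early genes (0.27), oxidative phosphorylation (0.22), pericytes and vascular smooth muscle (0.21) and itaconate, TCA cycle and related enzymes (0.14). With an estimated correlation the camera adjusted p was over the threshold for inflammasome and pyroptosis (0.115), activated microglia and macrophages (0.234), activated endothelium (0.0524), choroid plexus and ependyma (0.115), hormones (0.0521), oligodendrocyte precursors and newly formed oligodendrocytes (0.115), immediate early genes (0.383), oxidative phosphorylation (0.252), pericytes and vascular smooth muscle (0.249) and itaconate, TCA cycle and related enzymes (0.383).

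Inflammatory genes rose at 1 day while Y-linked transcripts separated PBS from LPS libraries, so a difference of sex might have produced the rise. Of 109 tested inflammatory genes 89 rose at 1 day (median log2 fold change 1.61), and 83 of these fell back at 7 days, where Y-linked transcripts were as high. Their median from 1 day to 7 days was -1.69 (quartiles -2.71 and -0.95). Against PBS it was -0.06 at 7 days, with 16 of the 89 called above PBS and 18 below. This argues against sex as the source of the rise of these genes as a set. If PBS mice were female and LPS mice male, X homologues of Y-linked genes that escape inactivation would be lower after LPS. All 4 were lower at 7 days (median -0.20) but at 1 day 1 rose and 1 fell (0.00). Over both LPS groups the median was -0.16. These 4 genes do not decide the question, and tissue makeup may shift them too. The Y-linked counts, 1, 0 and 0 in PBS against 1060 to 1669 per LPS library, show PBS tissue almost without such transcripts. Counts this low in all 3 PBS libraries argue against male tissue there, whereas every LPS library carried these transcripts. Sex as marked by Y-linked transcripts thus coincides with treatment in both comparisons against PBS. Whether a label was mixed up was not tested. Xist, set beforehand as a check on sex, is not reported here.

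Cerebellar and hindbrain transcripts were higher in each of the 3 libraries at 7 days than in any 1 day library. The mean log2 CPM of the cerebellum list was 2.48 to 2.56 in PBS, 2.35 to 2.42 at 1 day after LPS and 6.47 to 6.54 at 7 days, and that of the hindbrain list, which stayed low, was -2.73 to -2.64, -2.44 to -2.08 and 1.04 to 1.14. Tissue of other brain regions in these samples might bring them. All 32 tested members of the first lists rose against PBS, a void test since the lists were written from the pattern, and 10 of 11 tested members of the second list rose, as that explanation requires. The other 6 of its 17 members had too few counts, and since 7 day counts help a gene to pass the filter, the 8 members that pass on the 1 day libraries alone were also taken, of which 8 rose. Both LPS groups carry Y-linked transcripts. The lowest log2 fold change of the first cerebellum list between them was 0.53, a void test too, since that list was written from the pattern. Of the second list, 10 of 11 tested members were higher at 7 days than at 1 day (median 2.11). This argues against sex for these genes, a reading chosen after the values were seen. A biological cause at 7 days coincides with the group and was not tested.

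Striatal transcripts were lower in both LPS groups than in PBS (mean log2 CPM 7.16, SD 0.012, in PBS, 6.49, SD 0.018, at 1 day and 6.04, SD 0.028, at 7 days). A smaller share of striatal tissue may lower them: all 15 members of the first list lay below PBS at both times, a void test, and all 12 of the second list did too, as that explanation requires. Lowered expression in striatal neurons after LPS would look the same and stays open. Between 7 days and 1 day, at a like Y-linked level, 11 of 15 members of the first list were lower, a void test since its totals were known. Of the second list 9 of 12 were lower and 1 was higher (median -0.39). This argues against sex for that part, a reading chosen after the values were seen. At 1 day 13 of 15 members of the first list were lower than in PBS, where sex, treatment and tissue share cannot be told apart because no PBS library carries Y-linked transcripts.

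Splits of 3 libraries against 3 number 10, too few for a share under 0.05. By edgeR the real split called 7289, 5287 and 8399 genes in the 3 comparisons and the highest other split 0 in each, and 1 split in each comparison, the real one, reached its count. At unadjusted p under 0.05 the other splits held 187 to 384, 236 to 541 and 167 to 304 genes.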

How the results depend on the processing

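The test against a fold of 1.5 and the fit on autosomes were chosen after the results were seen. Counts of changed genes stayed within 1.5 times under DESeq2 (6603, 4734 and 7826 in the order of the comparisons), limma-voom (7211, 5282 and 8350), 6 libraries alone (7307, 5174 and 8479), autosomes (7068, 5158 and 8150) and leaving out each library (6371 to 7484, 4629 to 5304 and 7584 to 8531). They fell to 772, 541 and 1139 with a 2-fold change required and to 647, 539 and 1256 in the test against a fold of 1.5, since many changes were small. Replicate numbers do not pair the samples, and a block on them gave 7144, 5139 and 8270 genes and 23, 16 and 20 lists. Scaling by library size turned the split of rises and falls in each comparison (3446 up and 3878 down, 3183 and 2326, 4867 and 3680), and upper-quartile scaling did so at 1 day against PBS and at 7 days against 1 day. The split at 7 days turned too with the filter of 1 CPM (2684 up and 2612 down against PBS, 4144 and 4127 against 1 day), on autosomes (2609 and 2549, 4086 and 4064) and, against 1 day, with 6 libraries alone (4289 and 4190).

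Of the 24, 16 and 19 lists called by camera, 11, 7 and 10 passed with an estimated correlation. By fry 30, 32 and 37 of all 40 lists passed, among them all 24, 16 and 19, with 0 reversed; the estimate allows for genes of a list moving together. Camera calls that ended without 1 library were, at 1 day, hippocampus and dentate gyrus (camera adjusted p = 0.0936 without PBS replicate 3, 0.133 without LPS 1 day replicate 2 and 0.0696 with the block), cell cycle (0.0554 without PBS replicate 1), inflammasome and pyroptosis (0.0579 without PBS replicate 3) and oligodendrocyte precursors and newly formed oligodendrocytes (0.0525 without LPS 7 day replicate 3).

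The median share of the 1 day change left at 7 days ranged from 0.09 to 0.14 for rises and from 0.257 to 0.334 for falls when each library was left out. With no limit on the fold change it was 0.176 for falls, from 3590 genes in place of 179, and the cause was not tested. With the block the shares were 0.098 and 0.306. For Acod1 at 7 days against PBS the log2 fold change ranged from -2.66 without LPS 7 day replicate 2 (edgeR quasi-likelihood adjusted p = 0.475) to 1.01 without LPS 7 day replicate 3, because its 3 counts lie in replicate 2. The sign against PBS turned in 2 of 9 such fits. At 7 days against 1 day it ranged from -6.35 to -2.68 and turned in 0. The -2.66 and the -6.35 come from a 7 day group left without a count, so their sizes are not measured. Named genes other than Acod1 held their direction and their side of the edgeR threshold in 876 of 876 values under the alternatives run for them and with each library left out. They had been picked from the same data for small p-values or large changes, which favours this result. Library size and upper-quartile scaling were not run for them. Depth limits what can be said of Acod1, with 29 counts of Acod1 over the 3 libraries at 1 day.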

Other observations

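Genes of hormones and the olfactory bulb and cortex lists were chosen after their values were seen. Circadian clock genes differed between the groups, in which day, treatment and tissue makeup partly coincide. At 1 day after LPS 10 of 19 rose (11 adjusted over the list alone), 2 fell and 7 did not pass (median 0.11, camera adjusted p = 0.0114, and camera adjusted p = 0.0646 with an estimated correlation), Dbp, a clock output gene, at -1.03 ± 0.08 and Cry1 at 0.96 ± 0.09. At 7 days 14 fell below PBS, 4 rose and 1 did not pass (median -0.40, camera adjusted p = 0.000277), and from 1 day to 7 days 16 fell, 1 rose and 2 did not pass (median -0.41, camera adjusted p = 1.69e-05). Over that interval Cry2, a repressor of the clock, was at -0.87 ± 0.05 and Tef at -0.65 ± 0.04. The labels used here give no time of day.

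Hormone genes followed another course. The list holds hypothalamic and pituitary hormones, so a varying share of tissue outside the PVT may change these levels, which was not tested. Prl had 4.59 ± 0.084 CPM in PBS, 0.718 ± 0.187 CPM 1 day after LPS and 9.9 ± 1.09 CPM at 7 days, growth hormone, Gh, 3.07 ± 0.468, 1.06 ± 0.137 and 11 ± 1.29 CPM. Of 11 tested members of the hormone list 10 fell at 1 day and 1 did not pass (median -0.85, camera adjusted p = 0.000135, and camera adjusted p = 0.075 with an estimated correlation). At 7 days against PBS 3 rose (4 adjusted over the list alone), 2 fell and 6 did not pass (median -0.02, camera adjusted p = 0.517). Between 7 days and 1 day 9 rose and 2 did not pass (median 0.60, camera adjusted p = 0.000546, and camera adjusted p = 0.0521 with an estimated correlation). Hcrt, the orexin precursor, rose over that interval by 1.74 ± 0.10.

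Potassium and calcium channels had 8 up (9 adjusted over the list alone), 12 down and 11 not passed of 31 at 1 day (median -0.01, camera adjusted p = 0.682). They had 8 up, 13 down (15 adjusted over the list alone) and 10 not passed at 7 days against PBS (-0.13, camera adjusted p = 0.155), and 11 up, 13 down (14 adjusted over the list alone) and 7 not passed between 7 days and 1 day (-0.08, camera adjusted p = 0.525). Kcnq5 fell over the week by 1.18 ± 0.06 and the leak channel Kcnk3 rose by 1.32 ± 0.08. Cell cycle genes rose at 1 day in 6 of 16 cases with 10 not passed (median 0.35, camera adjusted p = 0.0268), with camera adjusted p = 0.146 with an estimated correlation and 0.0554 without PBS replicate 1. They had 1 up (0 adjusted over the list alone), 1 down and 14 not passed at 7 days against PBS (-0.04, camera adjusted p = 0.88). Between 7 days and 1 day they had 6 down (5 adjusted over the list alone) and 10 not passed (-0.43, camera adjusted p = 0.0523, and without 1 library as low as 0.024 for cell cycle without LPS 1 day replicate 2). Mki67 was at -1.08 ± 0.22.

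Heat shock and unfolded protein response genes had 4 up, 7 down (8 adjusted over the list alone) and 11 not passed of 22 at 1 day (median -0.08, camera adjusted p = 0.498). They had 7 up, 3 down and 12 not passed at 7 days against PBS (0.12, camera adjusted p = 0.147) and 11 up, 4 down and 7 not passed between 7 days and 1 day (0.16, camera adjusted p = 0.121). Glycolysis and hypoxia had 8 up, 8 down and 9 not passed of 25 at 1 day (-0.04, camera adjusted p = 0.849), 8 up, 5 down and 12 not passed at 7 days against PBS (0.04, camera adjusted p = 0.424) and 11 up, 6 down and 8 not passed between them (0.08, camera adjusted p = 0.3). Gapdh, which has near-identical copies whose shared reads were not measured, was at 2.44 ± 0.07 at 1 day. Members of this list ranged from -0.71 to 0.88 between 7 days and 1 day, so Gapdh was still above PBS at 7 days. It thus separated PBS from both LPS groups, which also differ in Y-linked transcripts. Ribosomal proteins had 3 up, 9 down and 14 not passed of 26 at 1 day (-0.04, camera adjusted p = 0.295), 9 up (10 adjusted over the list alone), 3 down and 14 not passed at 7 days against PBS (0.03, camera adjusted p = 0.373) and 10 up, 2 down and 14 not passed between them (0.05, camera adjusted p = 0.154).

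Blood cell lists were small. Erythrocytes had 1 up (0 adjusted over the list alone) and 4 not passed of 5 at 1 day (median 0.55, camera adjusted p = 0.364), 3 up, 1 down and 1 not passed at 7 days against PBS (0.65, camera adjusted p = 0.469) and 1 down and 4 not passed between them (0.01, camera adjusted p = 0.981). Of 3 tested neutrophil genes 1 fell at 1 day (1 up and 1 down adjusted over the list alone, median 0.08), 0 changed at 7 days against PBS (-0.14) and 1 rose and 1 fell between them (0.17), with no set test. Of 2 tested lymphocyte genes 1 fell at 1 day (2 adjusted over the list alone, median -0.75), 2 at 7 days against PBS (-1.44) and 1 between them (-0.69). Cd4 had 16.3 ± 1.48 CPM in PBS, 9.62 ± 1.04 CPM at 1 day and 4.78 ± 0.298 CPM at 7 days.

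The added lists gave these values at 1 day against PBS: cerebellum 1 up, 6 down and 13 not passed of 20 (median -0.17, camera adjusted p = 0.1), hindbrain 2 up and 10 not passed of 12 (1.31, 0.59 with 2 genes at their bound, camera adjusted p = 0.213) and cortex 5 up, 1 down and 9 not passed of 15 (0.08, camera adjusted p = 0.128). The olfactory bulb list of 7 had 3 down and 4 not passed at 1 day (-0.16, camera adjusted p = 0.1), 3 up, 3 down and 1 not passed at 7 days against PBS (0.23, camera adjusted p = 1) and 3 up, 2 down and 2 not passed between them (0.06, camera adjusted p = 0.269). All 4 Y-linked genes tested rose at both times against PBS (medians of at least 8.62 and 8.95, with 3 genes at their bound), and 1 rose between 7 days and 1 day (0.13). Their 4 X homologues had 1 up and 1 down at 1 day (0.00), 4 down at 7 days against PBS (-0.20) and 1 up and 3 down between them (-0.27). The second list of cerebellum and hindbrain had 5 of 11 down at 1 day (-0.03) and 10 up at 7 days against PBS and against 1 day (1.72 and 2.11). The second striatum list had 12 of 12 down at both times against PBS (-0.74 and -1.48) and 1 up and 9 down between them (-0.39).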
